A study of Mus musculus with 74 samples.

How the data were processed

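RNA was measured in white adipose tissue, brown adipose tissue and liver of male B6C3F1 mice on 74 Affymetrix mouse arrays, 1 array per mouse and tissue. The values used here are the deposited expression values: linear intensity per probe set after robust multi-array averaging (RMA), per the labels. The RMA version, the chip definition and the set of arrays averaged together are not given in the sources used here, and the deposited table holds no detection calls. The intensity ran from 7.44 to 39426 over all deposited values, and its log2 was taken before any test. Total RNA was isolated with Trizol and biotin-labelled cRNA was hybridised, per the labels.

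Of 45101 probe sets, 34945 had a single gene symbol in the platform annotation, 932 had several, 9160 had none and 64 were controls. No gene was named from a probe set with several symbols. Each of the 18193 genes was represented by its probe set with the highest mean over the 74 arrays. By the mouse numbers in the labels, the replicates of each group are distinct animals. The within-group correlation of log2 values ran from 0.9241 to 0.9958 over 138 pairs of arrays, with a median of 0.9912 and 0 identical pairs. For arrays, their number limits the precision of each value.

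Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) within each tissue and study, with 1 mean for each of the 4 groups of vehicle and treated mice on days 15 and 29. Treated mice were compared with the same study's vehicle mice of the same day. Benjamini-Hochberg adjusted p-values below 0.05 were called, with no fold threshold and no filter on dim genes. Changes are treated minus vehicle in log2 units with the standard error (SE) of the fit, and group values are means ± SD. Further contrasts tested whether an effect differed between days, between brown adipose tissue and liver of the troglitazone study (40 arrays), and between troglitazone and Elmiron in liver (40 arrays). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

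The 44 lists of pathway genes and cell type markers were written in advance, with 625 of 688 entries measured. Lists were tested with camera in limma at an inter-gene correlation of 0.01, with p-values adjusted over the 44 lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way or, in its mixed form, change in either direction, were run beside it. The tests, the lists, the other settings that open the next paragraph and the rule for naming genes were chosen before the data were examined. That rule named, for each of the 8 comparisons of treated with vehicle mice, the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap, up to 3 members of each list with a called member, and genes fixed for each study whatever their result. Genes outside the rule are described as chosen after their values were seen.

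The other settings were dropping the dimmer 50% of genes, quantile normalization, median centring, averaging the probe sets of a gene, limma's trended and robust eBayes, array weights, a fit of the 2 groups compared alone, a fold threshold of 1.5, the other study's vehicle livers, the animal as a block, and leaving out each array in turn. Settings that leave out libraries with the expression of another tissue were added after the data were seen, as were 13 lists of organ markers. Same-numbered brown adipose and liver arrays of the troglitazone study come from the same mice by the labels. Over the 15 mice with both tissues, the deviations from the group means correlated between the tissues from -0.135 to 0.151, over 0.1 in 1 mouse, and best with the own number in 6 mice.

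The fit was tested on data simulated from the arrays of the 8 comparisons, with 200 of 18193 genes changed, 50 at each of 4 folds. At 2-fold, recovery on days 15 and 29 was 88% and 84% in white and 82% and 90% in brown adipose tissue. In liver it was 94% and 100% with troglitazone and 94% and 98% with Elmiron. False calls made up 3.78% to 5.16% of all calls.

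The labels give no scan date or other batch. Each compound was given in a study of its own, so compound and study go together, and the doses differ. The planned comparisons used every sample, and fits without some libraries are named as such. Tumour counts, histology and cell proliferation indices are not analysed here.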

Results

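Male B6C3F1 mice received fenretinide (500 mg/kg, in the diet), troglitazone (1200 mg/kg, oral) or Elmiron (pentosan polysulfate, 1000 mg/kg, oral) for 15 or 29 days. Fenretinide is a synthetic retinoid, troglitazone activates PPARγ, and Elmiron is a sulfated polysaccharide drug. Hemangiosarcomas, tumours of endothelial cells, arise in the tissues profiled. The time course asked when changes tied to proliferation or to hypoxia appear there. White adipose tissue of the fenretinide study had 3 vehicle and 3 treated mice on day 15 and 4 of each on day 29. Brown adipose tissue and liver of the troglitazone study and liver of the Elmiron study had 5 vehicle and 5 treated mice on each day.

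Fenretinide raised Cyp26b1, Lrat and Rarb, genes of retinoid breakdown, storage and signalling, in white adipose tissue on day 15. As lists, p53 targets, cell cycle and DNA replication genes and endothelial markers were called higher by camera and adipocyte genes lower (the latter not without fenretinide mouse 59, adjusted p = 0.0811), none of them with an estimated correlation (smallest adjusted p 0.222). Genes of epithelial cells were among the largest rises, and general epithelium markers, a list written after the data were seen, were high in the 3 treated libraries (14 measured, 9 higher, median 2.56). In all, limma called 719 of 18193 genes, 595 higher and 124 lower, and in 715 of these the treated and vehicle values did not overlap. Over all genes 27.9% did not overlap, against a chance share of 10%.

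Cyp26b1, which encodes an enzyme that oxidises retinoic acid, went from 6.85 ± 0.18 to 10.90 ± 0.21 (n = 3 each), a rise of 4.05 ± 0.21 (SE, log2), or 16.6-fold (adjusted p = 1.89e-07). Lrat, whose product makes retinyl esters, rose by 1.60 ± 0.19 (adjusted p = 3.02e-04). The retinoic acid receptor gene Rarb rose by 0.88 ± 0.19 (adjusted p = 0.0211). These were the called genes among 20 measured genes of retinoid response and handling, of which 4 were higher and 2 lower when adjusted over the list alone. Camera did not call that list (median 0.10, adjusted p = 0.176), and fry gave an adjusted p of 0.0111.

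The p53 target Eda2r, a receptor of the TNF family, rose by 2.20 ± 0.22 (adjusted p = 6.94e-05). Mdm2, the ubiquitin ligase of p53, rose by 0.62 (adjusted p = 0.0111), and 2 of its 3 probe sets moved that way. Zmat3 rose by 0.76 (adjusted p = 0.0150) and Perp, which also builds desmosomes, by 3.08 ± 0.37 (adjusted p = 3.86e-04). Of 14 measured p53 targets, 4 rose, or 8 adjusted over the list alone. The list was called (median 0.64, camera adjusted p = 1.93e-05, fry 0.00431), but not with an estimated correlation (adjusted p = 0.222). The cell cycle inhibitor Cdkn1a changed by 0.71 (adjusted p = 0.0661) and was not called. The general epithelium markers were higher in the same libraries (median 2.56).

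Proliferation genes were called higher as a list on day 15. Of 29 measured genes of the cell cycle and DNA replication, 27 had a change above 0 and 9 were called higher, or 19 adjusted over the list alone. The helicase gene Mcm6 rose by 1.13 ± 0.16 (adjusted p = 0.00140), Uhrf1, which maintains DNA methylation at replication, by 1.06 ± 0.19 (adjusted p = 0.00785), and the ribonucleotide reductase gene Rrm2 by 2.35 ± 0.48 (adjusted p = 0.0150). Top2a rose by 1.60 ± 0.41 (adjusted p = 0.0479), with 2 of its 3 probe sets moving that way, while Mki67 changed by 2.04 ± 0.54 without a call (adjusted p = 0.0567). The list had a median of 0.72 (camera adjusted p = 6.01e-13, fry 0.0462), and adjusted p = 0.516 with an estimated correlation. The same libraries carried the epithelial genes described next (median of the general epithelium markers 2.56). Ccnd1, encoding cyclin D1 and chosen after its values were seen, rose by 2.56 ± 0.25 (adjusted p = 5.39e-05).

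Genes of epithelial junctions and membranes were among the largest rises. Prom1, a membrane protein of epithelial and stem cells, went from 6.57 ± 0.31 to 12.05 ± 0.28, a 44.7-fold rise (5.48 ± 0.18, adjusted p = 2.63e-09). Rises above 4.5 were also seen for Dsp of desmosomes (5.19), Cldn7 of tight junctions (5.05), Rnf128 (4.96), the potassium channel gene Kcnk1 (4.91), Cdh1, which encodes E-cadherin (4.75), and the arginase gene Arg2 (4.59). Calml3 rose by 5.25 with an SD of 2.51 between the treated mice. The cholangiocyte markers, epithelial genes that include Cldn7, had 5 measured members, of which 1 was called higher and 3 adjusted over the list alone (median 0.96, camera adjusted p = 0.00290, fry 5.44e-04). With an estimated correlation that list had an adjusted p of 0.222. None of these genes was raised in the white adipose tissue of treated mice on day 29.

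Endothelial markers were called higher as a list, and angiogenic growth factors were not. Emcn, a sialomucin of venous and capillary endothelium, rose by 0.94 ± 0.18 (adjusted p = 0.0103), the lymphatic receptor gene Flt4 by 0.74 ± 0.16 (adjusted p = 0.0212) and Mmrn2 of the endothelial matrix by 0.61 ± 0.14 (adjusted p = 0.0242). Of 26 measured endothelial markers, 4 rose, or 13 adjusted over the list alone (median 0.48, camera adjusted p = 4.33e-05, fry 0.121), and the list had an adjusted p of 0.560 with an estimated correlation. The general epithelium markers were higher in the same libraries (median 2.56). Pecam1 changed by 0.63 (adjusted p = 0.104) and the VEGF receptor gene Kdr by 0.61 (adjusted p = 0.116), neither called. Cd93, a surface receptor of endothelial cells chosen after its values were seen, rose by 1.07 (adjusted p = 0.0257). Of 23 angiogenic growth factors, 3 rose, and 6 rose and 3 fell adjusted over the list alone. Those called were Apln (1.21 ± 0.31, adjusted p = 0.0492), Angpt2 (1.05 ± 0.26, adjusted p = 0.0402) and Tgfb2 (0.80 ± 0.19, adjusted p = 0.0393). The list as a whole did not shift one way (median -0.05, camera adjusted p = 0.800), while its members changed in either direction by fry's mixed test (adjusted p = 1.38e-09).

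Hypoxia genes as a group were not called on day 15 (25 measured, 1 higher, 2 adjusted over the list alone, median 0.17, camera adjusted p = 0.221), and fry's mixed test gave an adjusted p of 0.00198. Ankrd37, a target of hypoxia-inducible factor 1, rose by 0.85 ± 0.19 (adjusted p = 0.0278). Vegfa changed by -0.54 ± 0.24 (adjusted p = 0.243) and the glucose transporter gene Slc2a1 by 0.47 (adjusted p = 0.108), neither called. Oxidative stress genes driven by Nrf2 had 2 of 14 members higher, also 2 adjusted over the list alone (median 0.20, camera adjusted p = 0.0162, fry 0.0111), with the epoxide hydrolase gene Ephx1 at 1.48 ± 0.25 (adjusted p = 0.00488). That list had an adjusted p of 0.222 with an estimated correlation, and was not called by camera without fenretinide mouse 59 (median 0.15, adjusted p = 0.0863). The general epithelium markers were higher in the same libraries (median 2.56). Acot1, a thioesterase gene driven by PPARα, rose by 2.49 ± 0.32 (adjusted p = 6.90e-04).

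Adipocyte genes were called lower as a list on day 15, in the same 3 libraries in which the general epithelium markers were higher (median 2.56). All 21 measured PPARγ and adipocyte genes had changes at or below 0 (median -0.23, camera adjusted p = 0.00162, fry 0.00575), with 2 called lower over all genes and 2 adjusted over the list alone, and adjusted p = 0.222 with an estimated correlation. The glycerol channel gene Aqp7 fell by 0.78 (adjusted p = 0.00712) and the lipase gene Pnpla2 fell by 0.41 (adjusted p = 0.0264). The amino acid carrier gene Slc7a10 fell by 1.06, the carbonic anhydrase gene Car4 fell by 2.01, the chemokine gene Cxcl9 fell by 2.05 and the opsin gene Opn3 fell by 0.99, each called. Leptin (Lep) changed by -1.28 ± 0.63 (adjusted p = 0.290). Erythroid genes (14 measured, 1 higher and 1 lower, 1 higher and 4 lower adjusted over the list alone) were lower as a list (median -0.28, camera adjusted p = 0.00725, fry 0.00620), with adjusted p = 0.222 with an estimated correlation. Without fenretinide mouse 59, camera called neither the adipocyte (median -0.19, adjusted p = 0.0811) nor the erythroid list (-0.33, 0.0769).

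Leaving out 1 array at a time gave 339 (without vehicle mouse 50) to 1023 called genes (without fenretinide mouse 59), and array weights called 2186. The share of higher among called genes was 82.8%, against 65.1% with array weights, 76.0% after quantile normalization and 78.1% after median centring.

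**Figure D1:**
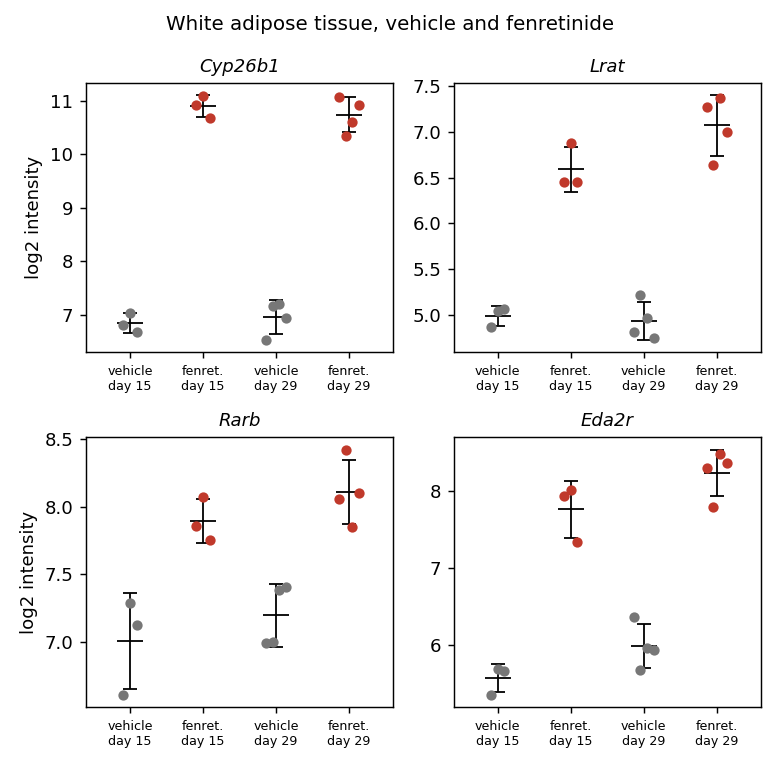
Log2 intensity of Cyp26b1, Lrat, Rarb and Eda2r in white adipose tissue of vehicle and fenretinide mice on days 15 and 29, with 1 point per mouse and the mean ± SD of each group. All 4 genes were higher in treated mice on both days, Cyp26b1 by 4.05 and 3.77 log2 units.

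On day 29 Cyp26b1, Lrat, Rarb and Eda2r were still higher in white adipose tissue of fenretinide mice, and the epithelial genes named for day 15 were not. Sox17, Sox18 and Id1, which encode transcriptional regulators, and the peptide hormone gene Adm were also higher, and leptin fell. Collagen and matrix genes were called lower as a list, with 7 of 23 lower one by one, but not with an estimated correlation (adjusted p = 0.435). In all, 244 genes were called, 75 higher and 169 lower, with no overlap between the groups in 241. Over all genes 8.75% did not overlap, against a chance share of 2.86%.

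Cyp26b1 rose by 3.77 ± 0.18 (adjusted p = 4.53e-07), Lrat by 2.14 ± 0.16 (adjusted p = 4.73e-05), Rarb by 0.91 ± 0.17 (adjusted p = 0.0244) and Eda2r by 2.26 ± 0.19 (adjusted p = 1.21e-04). Retinoid genes as a list were called (20 measured, 3 higher, 5 higher and 1 lower adjusted over the list alone, median 0.11, camera adjusted p = 0.00426, fry 0.00306). So were the p53 targets (14 measured, 4 higher, 7 adjusted over the list alone, median 0.37, camera adjusted p = 1.22e-06, fry 0.00610). Both had an adjusted p of 0.188 with an estimated correlation. The retinoid median became 0.06, 0.04 and 0.16 without vehicle mouse 81, 83 or 85. Cdkn1a rose by 1.0 ± 0.17 (adjusted p = 0.0206), Zmat3 by 0.69 ± 0.13 (adjusted p = 0.0323) and Mdm2 by 0.50 (adjusted p = 0.0400). Ccnd1 rose by 1.11 (adjusted p = 0.0322), less than on day 15 but without a called difference between days (adjusted p = 0.0520).

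The endothelial transcription factor genes Sox17 and Sox18 rose on day 29, by 0.91 ± 0.16 (adjusted p = 0.0206) and 0.98 ± 0.15 (adjusted p = 0.0144). Id1, which keeps endothelial cells from differentiating, rose by 1.37 ± 0.16 (adjusted p = 0.00217), against 0.25 on day 15 (adjusted p of the difference 0.0412). Of 26 endothelial markers, 23 had a change above 0 and 2 were called, or 10 higher and 1 lower adjusted over the list alone (median 0.34, camera adjusted p = 8.80e-08, fry 0.0941), with adjusted p = 0.368 with an estimated correlation. Without fenretinide mouse 91 the median of these markers was 0.18 (camera adjusted p = 2.32e-04). Cd93 rose by 0.97 (adjusted p = 0.0423), the pericyte channel gene Kcnj8 by 1.01 (adjusted p = 0.0469) and Mmp9, a gelatinase gene chosen after its values were seen, by 1.10 ± 0.15 (adjusted p = 0.00760).

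Hypoxia genes were not called as a list on day 29 (25 measured, 1 higher, also 1 adjusted over the list alone, median -0.06, camera adjusted p = 0.599), with an adjusted p of 0.00547 in fry's mixed test. The called member was Adm, which encodes the vessel-dilating peptide adrenomedullin and went from 9.75 ± 0.39 to 11.19 ± 0.57 (n = 4 each), a rise of 1.44 ± 0.27 (adjusted p = 0.0290). On day 15 Adm had changed by 0.62, and the days did not differ by test (adjusted p = 0.371). Vegfa changed by 0.30 (adjusted p = 0.583). The cell cycle list was not called (29 measured, 0 called, also 0 adjusted over the list alone, median -0.16, camera adjusted p = 0.118, fry 0.580). Inflammatory cytokine and adhesion genes were called as a list (21 measured, 20 above 0, 7 higher adjusted over the list alone and 0 over all genes, median 0.57, camera adjusted p = 5.56e-07). That list had an adjusted p of 0.368 with an estimated correlation, and its members Il6 (2.67 ± 0.92, adjusted p = 0.182) and Ccl2 (1.88, adjusted p = 0.345) were not called. Its mean score was 1.92, 0.98, -0.01 and 0.82 in treated mice 91, 93, 94 and 95 (-0.06 to 0.12 in vehicle mice), with neutrophil scores of 0.81, 0.37, 0.11 and 0.44 (-0.20 to 0.28) and acute phase scores of 1.17, 0.91, -0.42 and 1.79 (-0.52 to 0.85).

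Other large rises were those of Tmem255a (2.12 ± 0.24, adjusted p = 0.00217), the adhesion gene Clca2 (1.97 ± 0.34, adjusted p = 0.0206), Car8 (1.60 ± 0.26) and the T-box gene Tbx3 (1.48 ± 0.25).

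Single genes of the extracellular matrix fell. The aggrecanase gene Adamts5 fell by 1.56 ± 0.12 (adjusted p = 4.73e-05), more than on day 15 (-0.72, adjusted p of the difference 0.0412). The collagen VI genes Col6a1 and Col6a2 fell by 1.0 ± 0.10 and 1.29 ± 0.18 (adjusted p = 9.13e-04 and 0.00760), Col3a1 fell by 0.67 ± 0.12 and the microfibril gene Mfap4 fell by 1.60 ± 0.23. Of 23 collagen and matrix genes 7 fell, or 12 fell and 2 rose adjusted over the list alone (median -0.39, camera adjusted p = 1.82e-04, fry 0.0368), with adjusted p = 0.435 with an estimated correlation. The guidance gene Sema3c fell by 1.66 ± 0.17 (adjusted p = 9.13e-04), S100a4 of fibroblasts fell by 1.63 ± 0.26 and the natriuretic peptide clearance receptor gene Npr3 fell by 1.96 ± 0.36. Immunoglobulin Ighm fell by 1.81 ± 0.40 (adjusted p = 0.0462), but 4 of its 11 probe sets moved that way. Lep went from 13.19 ± 0.17 to 10.45 ± 1.14 (-2.74 ± 0.55, adjusted p = 0.0354), without a called difference from day 15 (adjusted p = 0.429). Lgals3 and Folr2 of macrophages and Mcpt4 of mast cells fell by 0.86, by 0.70 and by 0.84. Macrophage markers were not called as a list (24 measured, 1 lower, 3 higher and 7 lower adjusted over the list alone, median -0.20, camera adjusted p = 0.118). Mast cell markers were called lower (6 measured, 1 lower, 2 adjusted over the list alone, median -0.51, 0.0499, 0.453 with an estimated correlation), but not without any of 5 of the 8 arrays, at most 0.162 without vehicle mouse 81 (median -0.33).

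Metabolic lists were called by camera, but depended on single mice. Fatty acid oxidation genes (21 measured, median 0.28, camera adjusted p = 3.24e-04), oxidative phosphorylation genes (24 measured, median 0.11, 0.00426) and thermogenic genes of brown adipocytes (12 measured, median 0.76, 0.00662) were called higher. With an estimated correlation they had adjusted p of 0.453, 0.617 and 0.453. Without fenretinide mouse 93, whose library lay 0.55 of the way from brown to white fat, camera called none of the 3 (medians 0.11, 0.01 and 0.23, adjusted p = 0.0512, 0.438 and 0.272). Oxidative phosphorylation was also lost without vehicle mouse 81 or 83 (medians 0.08 and 0.06, 0.0624 and 0.0688), and the thermogenic median became 0.48 and 0.38. Cpt1a, the carnitine palmitoyltransferase of fatty acid oxidation, fell by 0.58 (adjusted p = 0.0354). The thermogenic shift followed single mice: the mean score of these genes, in log2 units around the day 29 vehicle mean, was 2.66 in fenretinide mouse 93 and 1.21 in vehicle mouse 85, and Ucp1 changed by 1.62 (adjusted p = 0.793) with SDs of 4.17 and 3.66. Hepatocyte gene scores were 2.02 in vehicle mouse 86, 0.99 in fenretinide mouse 93 and 3.03 in fenretinide mouse 95, against -1.06 to -0.04 in the other 5. Genes of cholesterol synthesis were called lower (19 measured, 0 above 0, median -0.35, camera adjusted p = 0.00740), with adjusted p = 0.617 with an estimated correlation. They were not called without vehicle mouse 86 (median -0.10, 0.423) or fenretinide mouse 94 (-0.21, 0.105).

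Leaving out 1 array at a time gave 51 (without vehicle mouse 83) to 237 called genes (without fenretinide mouse 91). An alternative added after the data were seen, without vehicle mouse 86 and fenretinide mouse 95, called 122 genes and kept 75 of the 244. Another one, without vehicle mice 85 and 86 and fenretinide mice 91 and 93, which were high in Ucp1 or muscle genes, left 2 mice in each group and called 64 genes, 35 of them among the 244. Of 44 lists camera called 13 higher and 4 lower, none of them with an estimated correlation (smallest adjusted p 0.188), and fry called 6.

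The effect differed between days by test for 242 genes, 11 with a higher and 231 with a lower effect on day 29. The effect on Prom1 fell by 5.56 (adjusted p = 9.91e-08), on Dsp by 5.39 (adjusted p = 1.16e-05), on Cldn7 by 5.10 (adjusted p = 1.40e-05) and on Kcnk1 by 4.96 (adjusted p = 1.43e-07). Among proliferation genes, the effect on Mcm6 was lower on day 29 (adjusted p = 0.00357), as was that on Uhrf1 (adjusted p = 0.0423). Those on Rrm2 (0.0731) and Mki67 (0.185) were not called. The cell cycle list as a whole was called lower (median -1.06, camera adjusted p = 3.35e-12, 0.648 with an estimated correlation), and so were the cholangiocyte markers (median -1.10, 4.18e-04, 0.147 with an estimated correlation). Cyp26b1 (adjusted p = 0.670), Lrat (0.322), Rarb (0.973) and Eda2r (0.944) gave no called difference. Of the genes higher on day 15, 30 were also higher on day 29, against 2.45 for independent lists, and 18 were lower on both days, against 1.15.

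Troglitazone changed few genes in brown adipose tissue by the planned fit. G0s2, Enc1, Aatk and Ephx2 rose on both days, and the clock output gene Dbp fell on day 15. On day 29 a pair of libraries, vehicle mouse 82 and troglitazone mouse 95, lacked brown adipocyte genes. Set against the vehicle median of each gene, hepatocyte markers had a median of 5.30 in mouse 82 and 0.87 in mouse 95, and mesothelial markers 3.25 and 2.19. A fit without these mice, added after the data were seen, called more genes on both days, while endothelial markers did not shift as a list. On day 15 limma called 11 genes, 9 higher and 2 lower, and on day 29 it called 10, 5 higher and 5 lower. In all 21 the groups did not overlap. Over all genes 3.25% did not overlap on day 15 and 0.759% on day 29, against a chance share of 0.794%.

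Sgk2, encoding a kinase close to the glucocorticoid-induced kinase SGK1, went from 6.64 ± 0.57 to 8.94 ± 0.33 on day 15 (n = 5 each), a rise of 2.30 ± 0.36 (adjusted p = 0.0175). On day 29 it changed by 0.66 without a call, and the days did not differ by test (adjusted p = 1). The peroxisomal thiolase gene Acaa1b rose by 1.20 ± 0.19 (adjusted p = 0.0175), and changed by 0.92 on day 29 (adjusted p = 0.0784). G0s2, an inhibitor of triglyceride lipolysis, rose by 0.95 ± 0.15 on day 15 (adjusted p = 0.0175) and by 0.95 on day 29 (adjusted p = 0.0241). Enc1 rose by 1.0 ± 0.12 and 0.69 (adjusted p = 0.00172 and 0.0353), Aatk by 0.81 ± 0.13 and 0.84 (0.0178 and 0.0241), and the epoxide hydrolase gene Ephx2 by 0.44 ± 0.07 and 0.40 (0.0147 and 0.0296). The clock output gene Dbp fell by 1.88 ± 0.34 on day 15 (adjusted p = 0.0395), and changed by -1.37 on day 29 (adjusted p = 0.169). Dixdc1 of Wnt signalling fell by 1.12 ± 0.18 on day 15 (adjusted p = 0.0175). On day 29 the thiamine carrier gene Slc19a2 fell by 0.67 ± 0.08 (adjusted p = 0.00284), Podxl of vascular endothelium fell by 0.66 (adjusted p = 0.0416), the pericyte gene Kcnj8 fell by 0.52 (adjusted p = 0.0416) and the stem cell factor gene Kitl fell by 0.48 (adjusted p = 0.0317).

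Camera called hypoxia genes lower as a list on day 15, when 5 of 25 measured members had a change above 0 (median -0.10, camera adjusted p = 0.00804, 0.0805 with an estimated correlation, fry 0.299), with 0 called over all genes and 1 lower adjusted over the list alone. On day 29 the median was -0.08 (0.0368, 0.168 with an estimated correlation, fry 0.280), with 0 called either way, and camera lost the list when any of 5 of the 10 arrays was left out, at most to 0.258 without troglitazone mouse 95. Vegfa changed by -0.15 on day 15 and was not called on either day. Cell cycle genes were not called on day 15 (29 measured, 0 called, median -0.02, camera adjusted p = 0.691, fry 0.980). On day 29 they were called higher by camera (median 0.14, 0.0368), but not with an estimated correlation (adjusted p = 0.816), and 0 members passed, also adjusted over the list alone. They were lost when any of 5 of the 10 arrays was left out, at most to 0.867 without troglitazone mouse 95 (median 0.02). Clock genes were called lower as a list on day 15 (14 measured, 1 lower, 7 adjusted over the list alone, median -0.32, camera adjusted p = 6.00e-05), with adjusted p = 0.0882 with an estimated correlation. Fatty acid synthesis genes were lower (12 measured, 0 above 0, median -0.13, 0.00647, 0.550 with an estimated correlation) and fatty acid oxidation genes higher (21 measured, 1 called, median 0.11, 0.0174, 0.947 with an estimated correlation). Smooth muscle and pericyte markers were called lower as a list on day 29 (10 measured, 1 lower, median -0.32, camera adjusted p = 0.00142), with adjusted p = 0.168 with an estimated correlation and a median of -0.10 without vehicle mouse 82. Pparg itself changed by -0.49 on day 15 (adjusted p = 0.209).

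Without vehicle mouse 82 and troglitazone mouse 95, limma called 173 genes on day 15 (131 higher, 42 lower) and 198 on day 29 (107 higher, 91 lower), and kept all 11 and all 10 genes of the planned fit. On both days 49 genes were higher (expected for independent lists 0.771) and 22 lower (0.210). The genes of this paragraph were chosen after their values were seen, apart from Vegfa, Angptl4 and Pparg. Rbp7, a retinol-binding protein gene of vessel endothelium and a PPARγ target, rose by 1.18 ± 0.10 on day 15 (adjusted p = 1.30e-05) and 1.19 ± 0.11 on day 29 (adjusted p = 6.70e-05). Over its alternatives, adjusted p ran from 1.39e-06 to 0.230 on day 15 and from 6.70e-05 to 1 on day 29. The tight junction gene Cldn5 rose by 1.52 ± 0.18 and 1.04 ± 0.20 (adjusted p = 2.07e-04 and 0.0189, ranges 2.29e-05 to 0.711 and 0.0189 to 1). Gpr182 of lymphatic and sinusoidal endothelium rose by 0.85 ± 0.08 and 0.69 ± 0.09 (3.03e-05 and 0.00106, ranges 1.41e-05 to 0.376 and 0.00106 to 1). Thbd, encoding the anticoagulant receptor thrombomodulin, fell by 0.71 ± 0.08 and 0.95 ± 0.09 (1.17e-04 and 4.63e-05, ranges 1.17e-04 to 1 and 4.63e-05 to 1). Myct1, a membrane protein of endothelial cells, fell by 0.68 ± 0.10 and 0.95 ± 0.11 (0.00162 and 4.52e-04, ranges 4.16e-04 to 0.603 and 4.52e-04 to 1). Pdgfb, by which endothelial cells recruit pericytes, fell by 0.55 and 0.61 (0.0166 and 0.0204, ranges 0.00854 to 0.358 and 0.0113 to 0.540). In this fit Vegfa fell by 0.54 ± 0.11 on day 29 (adjusted p = 0.0213, range 0.0213 to 1). Angptl4, a lipoprotein lipase inhibitor and PPAR target, rose by 0.49 and 0.54 (0.0379 and 0.0410, ranges 0.00610 to 1 and 0.0355 to 1). Pparg fell by 0.49 on day 15 (0.0104, range 0.00762 to 0.481).

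Endothelial markers did not shift together in that fit. On day 15 their median was 0 (26 measured, 1 higher, 2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.895), and on day 29 it was -0.06 (1 higher and 2 lower, 4 and 4 adjusted over the list alone, 0.286). Pericyte and smooth muscle markers were called lower as a list on day 29 (10 measured, 2 lower, 5 adjusted over the list alone, median -0.34, camera adjusted p = 1.99e-05, fry 0.00299, 0.119 with an estimated correlation). Sinusoidal endothelial markers, among them Gpr182, were called higher as a list (9 measured, 1 higher, also 1 adjusted over the list alone, median 0.28, 0.00524, fry 0.00299, 0.119 with an estimated correlation). The hypoxia list stayed lower on day 15 (1 lower, also 1 adjusted over the list alone, 8.42e-04, fry 0.00880, 0.0719 with an estimated correlation). Its member Bhlhe40, a hypoxia-induced repressor of clock genes, fell by 1.80 ± 0.19 (adjusted p = 9.07e-05, range over alternatives 2.52e-05 to 0.663).

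The planned fit depended on single arrays. Leaving out 1 array gave 2 (without troglitazone mouse 54) to 10 called genes (without troglitazone mouse 55) on day 15, and 2 (without troglitazone mouse 93) to 74 (without vehicle mouse 82) on day 29, with 39 without troglitazone mouse 95. Of 44 lists camera called 2 higher and 4 lower on day 15 and 4 higher and 8 lower on day 29, none of them with an estimated correlation (smallest adjusted p 0.0805 and 0.0758), and fry called 0. Limma called 0 genes for a difference between days (207 at an unadjusted p below 0.05), camera called 8 lists higher and 3 lower, none with an estimated correlation (smallest adjusted p 0.734), and fry 0.

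**Figure D2:**
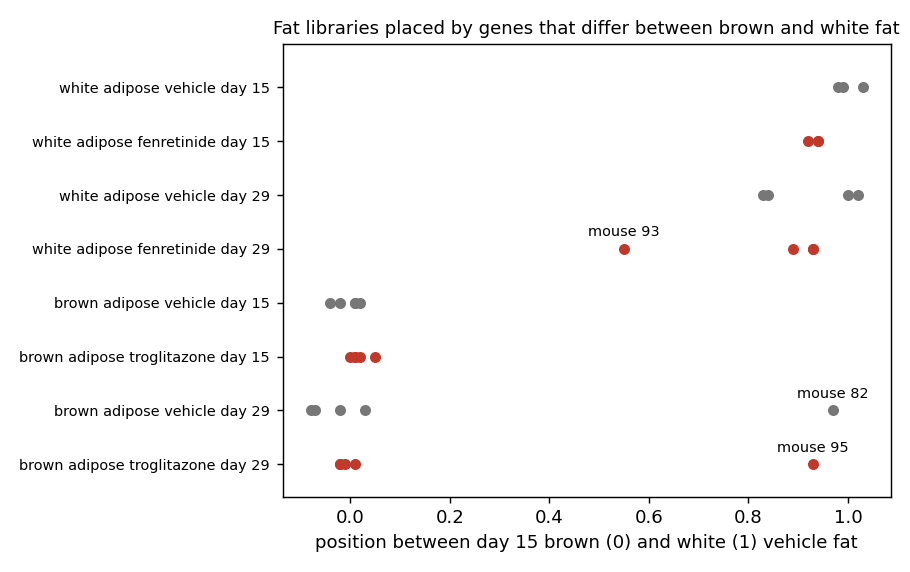
Position of each adipose library between brown (0) and white (1) vehicle fat of day 15, as the median share of the way over 460 genes that differ between them, with 1 point per mouse and groups on the y axis. Brown adipose libraries of mice 82 and 95 lie at 0.97 and 0.93, while the other brown adipose libraries lie from -0.08 to 0.05.

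**Figure D3:**
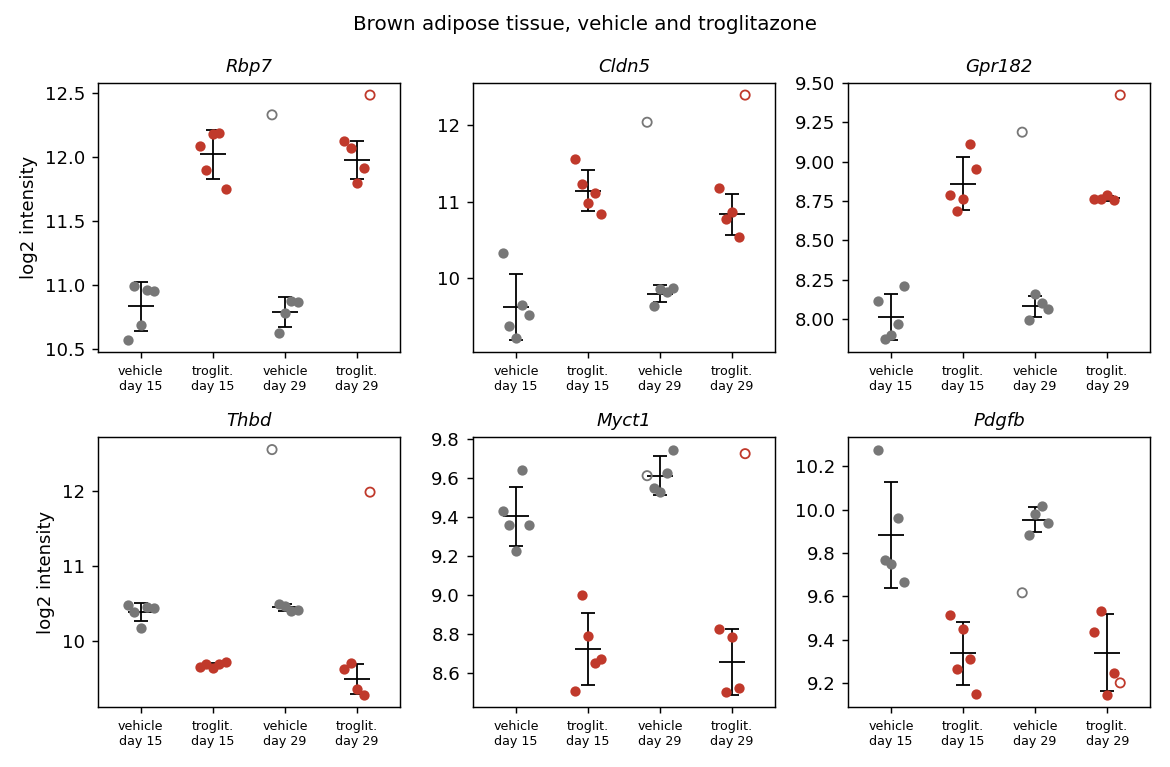
Log2 intensity of Rbp7, Cldn5, Gpr182, Thbd, Myct1 and Pdgfb in brown adipose tissue of vehicle and troglitazone mice on days 15 and 29, with 1 point per mouse and bars for mean ± SD. Open circles are mice 82 and 95, which are left out of the day 29 mean, and Rbp7, Cldn5 and Gpr182 were higher and the other 3 genes lower in treated mice of both days.

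In liver, troglitazone raised Cyp2b10, Pltp and Rdh16 on both days and Cd36 on day 29. Cyp2b10, a barbiturate-inducible cytochrome P450 gene, had the largest rise among called genes on both days, and Cd36 the smallest p on day 29. Proliferation and hypoxia genes were not called as lists. Limma called 4 genes on day 15, all higher, and 21 on day 29, 17 higher and 4 lower. The groups did not overlap in 4 and 17 of these, and over all genes in 2.09% and 1.07%, against a chance share of 0.794%.

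Cyp2b10 went from 9.25 ± 0.36 to 11.92 ± 0.35 on day 15 (n = 5 each), a rise of 2.67 ± 0.25 (adjusted p = 6.06e-06), and rose by 1.98 ± 0.25 on day 29 (adjusted p = 6.05e-04). The phospholipid transfer protein gene Pltp rose by 1.21 ± 0.14 and 1.0 (adjusted p = 9.15e-05 and 0.00111), and the retinol dehydrogenase gene Rdh16 by 0.74 ± 0.10 and 0.80 (0.00208 and 8.24e-04). Acaa1b rose by 0.53 ± 0.08 on day 15 (adjusted p = 0.00208). The fatty acid carrier gene Cd36, a PPARγ target, rose by 1.75 ± 0.22 on day 29 (adjusted p = 6.05e-04) and changed by 1.04 ± 0.22 on day 15 (adjusted p = 0.144), and the days did not differ by test (adjusted p = 0.651). Vnn1, a pantetheinase gene of the PPARα response, rose by 1.29 ± 0.23 on day 29 (adjusted p = 0.0219). Fitm1 of lipid droplets rose by 0.97 (adjusted p = 0.0286), Serpinb1a by 0.98 ± 0.15 (adjusted p = 0.00738), the repair gene Rad51b by 1.55 ± 0.29 (adjusted p = 0.0307), and the dynein gene Dnaic1 fell by 1.09 ± 0.17 (adjusted p = 0.00763). Genes not called included Cyp4a14 of the PPARα response (2.40 ± 0.55 and 1.98, adjusted p = 0.310 and 0.277), Pparg (0.16 on day 15) and Cyp3a11 (0.04 on day 15).

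Xenobiotic metabolism genes were called higher as a list on day 15: all 14 measured members had a change above 0, with 1 called, or 6 adjusted over the list alone (median 0.17, camera adjusted p = 3.84e-11, fry 1.23e-04). It was the only list called with an estimated correlation in the 8 comparisons of treated with vehicle mice (adjusted p = 0.00145). On day 29 its median was 0.01 (camera adjusted p = 0.102), without a difference between days with an estimated correlation (adjusted p = 0.884). Fry's mixed test called 3 lists that day: this one, PPARγ and fatty acid oxidation genes. Fatty acid synthesis genes were called higher as a list on both days (12 measured, 0 called, 4 and 3 adjusted over the list alone, medians 0.27 and 0.21, camera adjusted p = 3.23e-07 and 0.00158), with adjusted p of 0.121 and 0.535 with an estimated correlation. Acute phase genes had a median of 0.30 on day 15 (16 of 16 above 0, 0 called, 4.37e-05, 0.580 with an estimated correlation). Without troglitazone mouse 54 or 55 that median was 0.18 or 0.16. In all, camera called 13 lists higher and 4 lower on day 15 and 4 higher and 1 lower on day 29. Among the others of day 15 were inflammatory cytokine and adhesion genes (21 measured, 0 called, 1 adjusted over the list alone, median 0.10, 1.44e-04, 0.368 with an estimated correlation) and fatty acid oxidation genes (21 measured, 1 called, 4 adjusted over the list alone, median 0.02, 5.65e-05, 0.496 with an estimated correlation), the latter with medians of 0 to 0.05 when 1 array was left out. Interferon response (19 measured, 0 called, median 0.14, 0.00175, 0.664 with an estimated correlation) was lost without vehicle mouse 43 (0.0560) or troglitazone mouse 54 (0.0946). PPARγ and adipocyte genes (21 measured, 0 called, 2 adjusted over the list alone, median 0.05, 0.0171, 0.119 with an estimated correlation) were lost without any of 3 of the 10 arrays, at most to 0.0905 without vehicle mouse 43. Cholesterol synthesis on day 29 (19 measured, 0 called, median 0.10, 0.0284, 0.666 with an estimated correlation) was lost without any of 4 of the 10, at most to 0.433 without troglitazone mouse 92.

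Macrophage markers of liver were called higher on both days (24 measured, 0 called, 0 and 2 adjusted over the list alone, medians 0.14 and 0.45, 3.75e-04 and 3.66e-07), with adjusted p of 0.497 and 0.535 with an estimated correlation. So were Kupffer cell markers (7 of 7 above 0 on each day, 0 called, also 0 adjusted over the list alone, medians 0.29 and 0.44, 0.00935 and 0.00325), with adjusted p of 0.664 and 0.57 with an estimated correlation. Without troglitazone mouse 54, camera called neither on day 15 (macrophage median 0.06, adjusted p = 0.110, Kupffer 0.06, 0.483), and without troglitazone mouse 92 the macrophage median of day 29 was 0.27 (2.58e-04) and Kupffer markers were not called (0.20, 0.189). On day 15 Kupffer markers were also lost without vehicle mouse 43 (0.21, 0.0858), and the macrophage median was 0.23 without troglitazone mouse 55. Hepatic stellate cell markers were called lower on both days (0 of 7 above 0 on each day, 0 called, also 0 adjusted over the list alone, medians -0.18 and -0.17, 0.0160 and 0.0284), with adjusted p of 0.497 and 0.535 with an estimated correlation. They were lost without 2 of the 10 arrays on day 15 (at most to 0.160 without troglitazone mouse 55, median -0.09) and 3 on day 29 (at most to 0.156 without vehicle mouse 86, median -0.10), with medians of -0.30 and -0.37 without vehicle mice 87 and 88. Neutrophil markers were called higher on day 15 (9 measured, 0 called, median 0.18, 0.0149, 0.497 with an estimated correlation). Endothelial markers were called lower on day 15 (26 measured, 0 called, 1 lower adjusted over the list alone, median -0.14, 0.00390, 0.664 with an estimated correlation). Cell cycle genes were not called on either day (29 measured, 0 called, medians 0.01 and 0.07, camera adjusted p = 0.338 and 0.0990, fry 0.868 and 0.293). Hypoxia genes were not either (25 measured, 0 called, medians -0.01 on both days, 0.958 and 0.322, fry 0.906 and 0.433), with Vegfa at -0.07 and -0.05.

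Leaving out 1 array gave 4 to 6 called genes on day 15, and 7 (without vehicle mouse 85) to 50 (without vehicle mouse 87) on day 29, where array weights called 436. Vehicle mouse 88 of day 29 stood apart, with a mean correlation with its group of 0.9808 (0.9896 to 0.9906 in the other 4). Its actin 3' to 5' log2 ratio was 1.33 against 0.90 to 1.06 in these 4, while its Gapdh ratio of 0.20 was within their 0.18 to 0.27. Treated mouse 92 also had an actin ratio of 1.33 (0.76 to 1.21 in the other 4 treated mice), with a Gapdh ratio of 0.30 (0.13 to 0.31). Without mouse 88, in a fit added after the data were seen, limma called 7 genes on day 15 and 14 on day 29, of which 10 were among the 21. Limma called 0 genes for a difference between days (1363 at an unadjusted p below 0.05), camera 1 list higher and 1 lower, neither with an estimated correlation (smallest adjusted p 0.884), and fry 0.

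**Figure D4:**
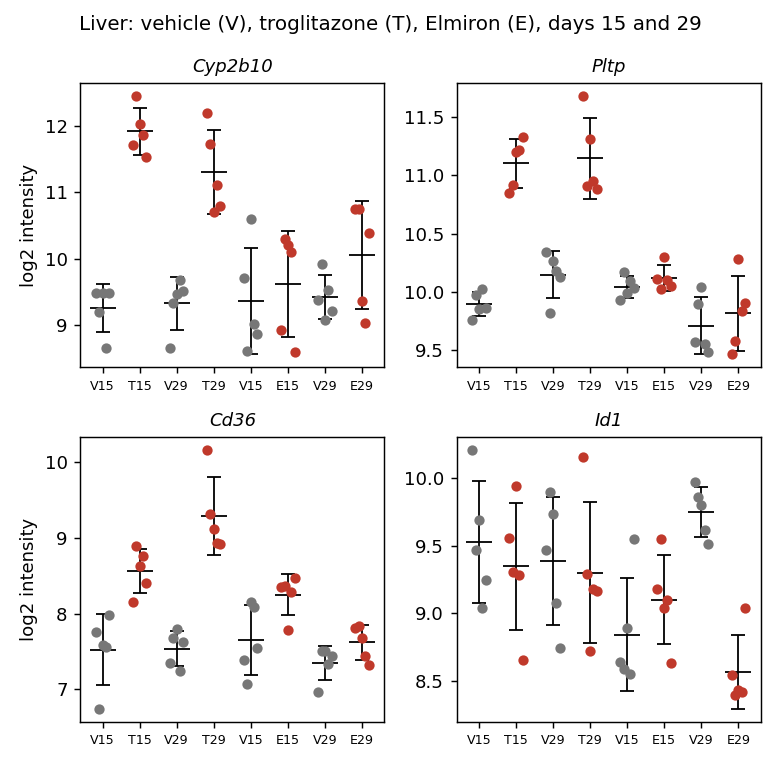
Log2 intensity of Cyp2b10, Pltp, Cd36 and Id1 in liver of vehicle and treated mice of the troglitazone and Elmiron studies on days 15 and 29, with 1 point per mouse and bars for mean ± SD. Cyp2b10 rose from 9.25 to 11.92 with troglitazone on day 15, and Id1 fell from 9.75 to 8.57 with Elmiron on day 29.

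Elmiron gave no called gene in liver on day 15. The lists of Kupffer cells and macrophages, of interferon response and of the cell cycle were called higher by camera, but no list was with an estimated correlation (smallest adjusted p 0.302). On day 29 Id1 fell, cholesterol synthesis genes were called higher as a list and fatty acid oxidation genes lower, both with an adjusted p of 0.441 with an estimated correlation. On day 15 limma called 0 genes (997 at an unadjusted p below 0.05, smallest adjusted p 0.549 for Rassf4, which was chosen after its values were seen), camera called 7 lists, all higher, and fry called 0. On day 29 limma called 1 gene. Groups did not overlap in 1.06% and 1.44% of genes, against a chance share of 0.794%.

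On day 15 all 7 Kupffer cell markers had a change above 0 (0 called, 6 adjusted over the list alone, median 0.56, camera adjusted p = 9.30e-09), with adjusted p = 0.302 with an estimated correlation. Among them Marco changed by 0.57 and Clec4f by 0.30. Of 24 macrophage markers 21 were above 0 (0 called, 6 adjusted over the list alone, median 0.27, 2.23e-09, 0.302 with an estimated correlation), among them the lysosomal glycoprotein gene Cd68 (0.53, adjusted p = 0.768). All 19 interferon response genes were above 0 (0 called, also 0 adjusted over the list alone, median 0.44, 9.09e-09, 0.474 with an estimated correlation), with a mean score of 0.90 in treated mouse 53 against 0.10 to 0.36 in the other 4. Of 29 cell cycle genes 22 were above 0 (0 called either way, median 0.17, 8.51e-05, 0.467 with an estimated correlation). Top2a was at 0.59 (adjusted p = 0.641, 1 of 3 probe sets higher) and Mki67 at 0.39. Endothelial markers (26 measured, 0 called, 2 adjusted over the list alone, median 0.13, 2.53e-04) and sinusoidal endothelial markers (9 of 9 above 0, median 0.19, 0.00570) were also called higher, both with adjusted p of 0.474 with an estimated correlation. Genes of fasting and glucocorticoid response had a median of 0.27 (12 of 13 above 0, 2.28e-04, 0.302 with an estimated correlation). Without treated mouse 53 the medians were 0.28 for interferon response (1.13e-04), 0.11 for the cell cycle (0.00647) and 0.17 for fasting genes (0.00347). The cell cycle median was 0.08 without vehicle mouse 41, and sinusoidal markers were not called without treated mouse 54 (0.13, 0.101). Hypoxia genes were not called (25 measured, median 0.05, camera adjusted p = 0.208, fry 0.477), and Vegfa changed by 0.18.

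On day 29 Id1, which encodes an inhibitor of differentiation driven by BMP signals, went from 9.75 ± 0.18 to 8.57 ± 0.27 (n = 5 each). It fell by 1.18 ± 0.18 (adjusted p = 0.0252). On day 15 it was 0.26 ± 0.18 above the vehicle mice without a call (adjusted p = 0.977), and the days did not differ by test (difference -1.44, adjusted p = 0.205). Id3 changed by -1.13 ± 0.21 without a call (adjusted p = 0.172). Cholesterol synthesis genes were all above 0 (19 of 19, 0 called, 6 adjusted over the list alone, median 0.27, camera adjusted p = 8.67e-08). In fatty acid oxidation 2 of 21 genes were above 0 (0 called, 1 lower adjusted over the list alone, median -0.16, 2.16e-07). Both lists had an adjusted p of 0.441 with an estimated correlation. Kupffer cell markers were lower than on day 15 (difference between days -0.51, camera adjusted p = 2.68e-05), but not with an estimated correlation (adjusted p = 0.584). Cell cycle genes (29 measured, 0 called, median 0.01, camera adjusted p = 0.421, fry 0.909) and hypoxia genes (25 measured, 0 called, 3 higher adjusted over the list alone, median 0.02, 0.631, fry 0.479) were not called. Hamp, encoding the iron hormone hepcidin that BMP signals also drive, changed by -0.19.

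Id1 was no longer called against the other study's day 29 vehicle livers (-0.82, adjusted p = 0.129, range over alternatives 0.0104 to 0.149), and was lost when any of 8 of the 10 arrays was left out, at most to 0.149 without vehicle mouse 81. Of 44 lists camera called 6 higher and 4 lower on day 29, none of them with an estimated correlation (smallest adjusted p 0.441), and fry called 0. For a difference between days limma called 0 genes (981 at an unadjusted p below 0.05), camera 1 list higher and 9 lower, none with an estimated correlation (smallest adjusted p 0.584), and fry 0.

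The effects of troglitazone in brown adipose tissue and liver differed for 4 genes on day 15. Cyp2b10 changed by -0.06 in fat and 2.67 in liver (difference -2.73 ± 0.33, adjusted p = 1.40e-05), Pltp by 0.04 and 1.21 (-1.17 ± 0.23, 0.0489), Sgk2 by 2.30 and 0.16 (2.14 ± 0.39, 0.0280) and the small GTPase gene Rhob by -0.75 and 0.18 (-0.93 ± 0.17, 0.0320). With the animal as a block Pltp was not called (adjusted p = 0.0604, range over alternatives 4.08e-06 to 0.142). On day 29 they differed for 3 genes: Cd36 by 0.09 in fat and 1.75 in liver (-1.66 ± 0.25, 0.00240), Cyp2b10 by 0.09 and 1.98 (-1.89 ± 0.33, 0.0152) and Ephx2 by 0.40 and -0.06 (0.46 ± 0.08, 0.0199). All were chosen after their values were seen. Camera with an estimated correlation called 3 lists, with lower effects in fat than in liver on day 15, and fry called 0 (smallest adjusted p 0.247). These were fatty acid synthesis (median -0.39, adjusted p = 0.0275 with an estimated correlation), xenobiotic metabolism (-0.41, 0.0275) and iron handling (-0.31, 0.0366). With that correlation the first 2 were lost without the fat of vehicle mouse 41 (adjusted p = 0.0604) or the liver of troglitazone mouse 54 (0.0621) or 55 (0.0604), and the second also without the fat of vehicle mouse 42 (0.0757). Iron handling was lost without any of 8 of the 20 arrays, at most to 0.103 without the fat of troglitazone mouse 54, with medians of -0.12 there and -0.13 without the fat of vehicle mouse 42. That fat had a hepatocyte gene score of 1.35, against -0.42 to -0.03 in the other 9 day 15 brown adipose libraries.

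Troglitazone and Elmiron were compared in liver through their effects against each study's own vehicles. On day 15 the effects differed for Pltp alone, which changed by 1.21 with troglitazone and 0.08 with Elmiron (difference 1.13 ± 0.19, adjusted p = 0.0156). On day 29 they differed for 17 genes, 16 of them higher with troglitazone. The fatty aldehyde dehydrogenase gene Aldh3a2 changed by 0.43 and -0.67 (1.10 ± 0.18, adjusted p = 0.00775), Fitm1 by 0.97 and -0.60 (1.56 ± 0.27, 0.00829), Vnn1 by 1.29 and -0.67 (1.96 ± 0.38, 0.0240), Acot1 by 0.31 and -1.19 (1.5 ± 0.32, 0.0465), Cd36 by 1.75 and 0.27 (1.48 ± 0.30, 0.0307) and Id3 by 0.43 and -1.13 (1.56 ± 0.30, 0.0240). Dnaic1 was the only one lower with troglitazone (-1.11). These genes too were chosen after their values were seen, and compound, dose and study go together here. Camera called 4 lists higher and 3 lower with troglitazone on day 15 and 5 higher and 1 lower on day 29, none with an estimated correlation (smallest adjusted p 0.300 and 0.904), and fry called 0. Without vehicle mouse 88 the 17 genes of day 29 became 7.

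Vehicle mice of days 15 and 29 gave 0 called genes by limma in white adipose tissue (1818 at an unadjusted p below 0.05), brown adipose tissue (398) and liver of the troglitazone (1185) and Elmiron (986) studies. The vehicle livers of both studies gave 0 on day 15 (565) and day 29 (2073). No other tool was run on the vehicle comparisons.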

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

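The tests of the 3 patterns weighed here (epithelial genes in white adipose tissue, brown adipose libraries without brown adipocyte genes, Kupffer cell genes in liver) and the lists of organ markers were chosen only after these results were seen, while the regroupings of arrays were planned.

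Single genes such as Ucp1 stood out in a pair of brown adipose libraries of day 29. In groups of 4 or 5 mice, a mouse was singled out where its gap to the nearest other mouse was above Dixon's 95% critical value, as held for 30 of 298 groups of named genes, 8 of them in vehicle mouse 82 and 6 in troglitazone mouse 95. Most genes singled out in these mice were named from a fit that left them out, so the choice of genes in part fixed that count. Over genes named by the rule set in advance it held for 13 of 216 groups, 2 of them in mouse 82 (Ucp1 and Vegfa) and 1 in mouse 95 (Ucp1), and chance alone gives about 1 in 20. In mouse 82 the uncoupling protein gene Ucp1 was at 5.91 (log2 intensity) against a mean of 15.01 in the other mice of its group, Vegfa at 10.59 against 11.95, Bhlhe40 at 9.31 against 11.67 and Pcdh12 at 7.83 against 8.46. Rbp7 was at 12.33 against 10.79, Gpr182 at 9.19 against 8.08, Cldn5 at 12.04 against 9.80 and Thbd at 12.55 against 10.45. In mouse 95 Ucp1 was at 8.10 against 14.94, Bhlhe40 at 8.52 against 10.97, Gpr182 at 9.42 against 8.77, Thbd at 11.99 against 9.50, Myct1 at 9.73 against 8.66 and Asns at 12.22 against 11.77.

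White fat collected or labelled in place of brown fat is a candidate explanation for these libraries. Over 460 genes that differ between white and brown adipose vehicle libraries of day 15, they lay 0.97 and 0.93 of the way from brown to white, while the other 18 brown adipose libraries lay from -0.08 to 0.05. A troglitazone effect is argued against, because the vehicle library lay at 0.97. By the actin 3' to 5' log2 ratio RNA degradation is argued against as well, since the higher of theirs was 0.52 and the highest of the other 18 was 0.98. The Gapdh ratio was 0.03 in mouse 82 but 0.18 in mouse 95, above the 0.01 to 0.11 of the other 18. Some degradation is therefore not excluded for mouse 95. Which of collection and labelling it was stays open, as does the source of the hepatocyte markers of mouse 82 (median 5.30 above the vehicle median, 0.87 in mouse 95) and of the mesothelial markers of both (3.25 and 2.19), and white adipose tissue of these mice is not analysed here.

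Among the other singled-out mice, again set against the mean of the others in the group, 3 p53 targets were low in fenretinide mouse 93 of white adipose tissue on day 29, with Cdkn1a at 11.89 against 12.53, Zmat3 at 9.56 against 10.11 and Mdm2 at 10.13 against 10.40. That library lay 0.55 of the way from brown to white fat, against 0.83 to 1.03 in the other white adipose libraries. In the same group Tmem255a in mouse 94 was at 8.70 against 7.76, and Cpt1a in mouse 95 at 10.78 against 10.38. In brown adipose tissue on day 15, troglitazone mouse 55 had Ddit3 at 9.10 against 9.50 and Aqp7 at 10.33 against 10.50, and vehicle mouse 43 had Thbd at 10.18 against 10.45. In liver of the troglitazone study, Rdh16 in treated mouse 55 was at 11.25 against 10.84 and Vnn1 in vehicle mouse 44 at 9.26 against 9.90 on day 15. On day 29 Rad51b in treated mouse 92 was at 8.66 against 6.92, and vehicle mouse 87 had Acaa1b at 13.99 against 14.13 and Vegfa at 9.01 against 9.51. In the Elmiron study Cd68 in treated mouse 53 of day 15 was at 9.03 against 8.25, Id1 in treated mouse 95 of day 29 at 9.04 against 8.45, and the acute phase gene Lcn2 in vehicle mouse 85 of day 29 at 12.18 against 6.56.

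Epithelial genes higher in white adipose tissue of fenretinide mice on day 15 may come from epithelial tissue collected with the fat. A fenretinide effect within the fat that lasts through day 29 is argued against, because the median change of the 595 higher genes was 0.03 on day 29 (median absolute deviation 0.25) and 1.10 on day 15. RNA degradation is argued against by actin 3' to 5' log2 ratios of 0.48 to 0.60 in the 3 treated libraries, within the 0.49 to 0.74 of the other 11 white adipose libraries or below it. Collected epithelial tissue and a response that had passed by day 29 cannot be told apart, because the mean score of the general epithelium markers was at least 2.09 in all 3 treated libraries and at most 0.23 in the other 11 white adipose libraries, so that it goes with treatment and day.

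Organ marker lists were compared in the same libraries, without settling a source. General epithelium markers (14 measured, 2 above the array median in vehicle fat, 2 in another list) had 9 members higher and a median of 2.56 on day 15 against -0.05 on day 29. Efferent duct and proximal epididymis markers (8 measured, 2 above the median, 2 in another list, 1 higher) had a median of 0.42, and vas deferens and distal epididymis markers (8 measured, 2 above the median, 1 in another list, 1 higher) had 0.99. The first had scores of 1.36 and 1.44 in mice 57 and 58 and 0.05 in mouse 59, the second 0.22, 0.12 and 2.36. The other lists had 7 to 10 measured members, 0 to 3 of them above the array median in vehicle fat and 0 to 5 in another list. Epididymis principal cell markers (median -0.10 on day 15), kidney tubule (-0.11), pancreas acinar (-0.17), seminal vesicle and prostate (-0.07), testis germ cell (0.03), intestine (-0.21), gallbladder and bile duct (-0.02), lung (-0.05), skin (-0.04) and mammary or salivary gland markers (-0.10) had 0 members higher by limma and, in the last, 1 lower. Camera and fry were not run on these lists. Of the 719 genes called, how many would remain without such tissue was not tested.

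Kupffer cell and macrophage genes stood higher in liver of Elmiron mice on day 15. The mean Kupffer score was 0.49 ± 0.30 in treated and 0 ± 0.26 in vehicle mice (n = 5 each). Chance is not excluded (exact two-sided permutation p = 0.0317, smallest possible 0.00794, 0.125 adjusted over the 9 scores tested). A low vehicle group is argued against by a median change of 0.71 against the other study's vehicle livers. A lower share of hepatocyte RNA cannot be told apart from a rise in Kupffer cells. Hepatocyte markers did not fall (median 0, 6 of 10 above 0), but endothelial and sinusoidal scores were higher too (0.13 and 0.20). The Kupffer score minus the endothelial, sinusoidal or stellate score (itself -0.15 ± 0.15) was 0.36 ± 0.40, 0.29 ± 0.41 or 0.64 ± 0.43 in treated mice. In vehicle mice it was 0 ± 0.23, 0 ± 0.20 or 0 ± 0.31 (n = 5 each). Exact permutation p adjusted over the 3 was 0.178, 0.183 and 0.0951. On day 29 the Kupffer score differed by -0.05 (exact permutation p = 0.770). With troglitazone the median change of these genes was 0.29 on day 15 and 0.44 on day 29. It was 0.06 without treated mouse 54 and 0.21 without vehicle mouse 43 (day 15) and 0.20 without treated mouse 92 (day 29), none called by camera.

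Effects also differed between groups by test. The response to fenretinide in white adipose tissue differed between days for 242 genes, such as Prom1, that to troglitazone between brown adipose tissue and liver for 4 genes on day 15 and 3 on day 29, such as Cyp2b10, and that of liver to troglitazone and Elmiron for 1 gene on day 15 (Pltp) and 17 on day 29.

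Other splits of the same arrays were fitted to see whether chance can be excluded for each count of genes. In white adipose tissue the 10 splits of day 15 are too few, with 719 genes in the real one and at most 0 in another. On day 29 only the real 1 of 35 splits gave 244 genes (highest other 15), so chance is excluded in this sense. It is also excluded for the difference between days there (1 of 100, 242 genes, highest other 231 in a split that kept the treated mice of each day and exchanged vehicle mice alone), for brown adipose tissue on day 15 (1 of 100, 11 genes, highest other 0), for liver with troglitazone on day 15 (2 of 100, 4 genes, highest other 4), for the tissue difference on day 15 (3 of 100, 4 genes, highest other 6 in a split that exchanged treated and vehicle fat) and for the compound difference on day 15 (2 of 100, 1 gene, highest other 1) and day 29 (2 of 100, 17 genes, highest other 132). Chance is not excluded for brown adipose tissue on day 29 (6 of 100, 10 genes), liver with troglitazone on day 29 (7 of 100, 21 genes), the tissue difference on day 29 (11 of 100, 3 genes) and liver with Elmiron on day 29 (7 of 100, 1 gene, highest other 2). In the first 3 of these, other splits called up to 2781 (mice 82 and 95 together), 3595 and 4535 genes. That points to a structure of the samples, as do the 132 for the day 29 compound difference. Where the real count is 0, all 100 splits give as many by construction and say nothing about chance, as for liver with Elmiron on day 15 (highest other 2) and the differences between days in brown adipose tissue (38), liver with troglitazone (1) and liver with Elmiron (5).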

How the results depend on the processing

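The settings that leave out libraries by their expression (brown adipose mice 82 and 95, liver vehicle mouse 88, white adipose mice 86 and 95 high in hepatocyte genes, and white adipose mice 85, 86, 91 and 93 high in Ucp1 or muscle genes) were chosen only after the results were seen, and the others before. Counts are genes called by limma unless stated, and where a count moved, the cause was not tested.

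Of the genes named in the text, 1966 values were recomputed over 213 pairs of gene and comparison, with leaving out any 1 array counted as 1 setting. Of these 1635 kept their direction and side of the threshold, 226 lost a call, 105 gained one and 0 reversed. By setting, calls were lost and gained in 49 and 11 of 188 values with 2 groups alone, 1 and 34 of 213 with array weights, 0 and 5 of 160 without the dimmer 50% of genes, 71 and 12 of 213 when any 1 array was left out, 13 and 0 of 213 with median centring, 8 and 1 of 213 with quantile normalization, 20 and 6 of 213 with averaged probe sets, 4 and 1 of 213 with trended robust eBayes, 5 and 4 of 51 with the other study's vehicles and 1 and 0 of 7 with the animal as a block. Without libraries chosen by their expression they were 0 and 29 of 64 (brown adipose mice 82 and 95), 11 and 0 of 46 (liver vehicle mouse 88), 18 and 1 of 86 (white adipose mice high in hepatocyte genes) and 25 and 1 of 86 (those high in Ucp1 or muscle genes). All 81 list medians tested under median centring kept their direction and size within the spread.

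Among retinoid and p53 genes, Cyp26b1, Lrat and Eda2r were called on both days in white adipose tissue under every setting run, and Rarb was lost in 2 of 9 settings on day 15 and 4 of 9 on day 29. In liver Cyp2b10 was called on both days under every setting run. Lep on day 29 of fenretinide was lost in 4 of 10 settings (adjusted p from 0.0198 to 0.110), as was Adm (0.0165 to 0.226).

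In white adipose tissue on day 15 the 719 genes became 358 without dim genes, 2186 with array weights and 350 with 2 groups alone. On day 29 the 244 became 402 without dim genes, 46 with 2 groups alone, 122 without the libraries high in hepatocyte genes and 64 without those high in Ucp1 or muscle genes. The 242 genes differing between days became 80 without dim genes, 746 with array weights and 107 without the libraries high in Ucp1 or muscle genes. The share of higher genes on day 29 was 30.7%, 36.8% after quantile normalization and 23.7% after median centring.

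In brown adipose tissue on day 15 the 11 genes became 19 without dim genes, 18 with averaged probe sets, 321 with array weights, 102 with 2 groups alone, 7 with a fold of 1.5 also required and 173 without mice 82 and 95. The last follows in part from the shared spread, as both mice are of day 29. On day 29 the 10 became 36 without dim genes, 170 with array weights, 0 with 2 groups alone, 6 with the fold threshold and 198 without mice 82 and 95.

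In liver with troglitazone the 4 genes of day 15 became 7 without dim genes, 8 after quantile normalization, 8 with averaged probe sets, 7 with trended robust eBayes, 19 with array weights, 10 with 2 groups alone, 17 with the other study's vehicles and 7 without mouse 88. The 21 of day 29 became 436 with array weights, 4 with 2 groups alone, 74 with the other study's vehicles and 14 without mouse 88. With Elmiron the 0 genes of day 15 became 5 with the other study's vehicles, and the 1 of day 29 (Id1) became 2 after quantile normalization, 7 with array weights, 2 with 2 groups alone and 42 with the other study's vehicles.

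For the tissue difference of troglitazone the 4 genes of day 15 became 8 without dim genes, 8 after quantile normalization, 2 after median centring, 10 with averaged probe sets, 1.5e+02 (rounded to 2 digits) with array weights and 21 without mice 82 and 95, and the 3 of day 29 became 124 with array weights and 49 without mice 82 and 95. For the compound difference the 1 gene of day 15 became 2 after quantile normalization, 0 with averaged probe sets and 2 with array weights, and the 17 of day 29 became 9 after median centring, 912 with array weights and 7 without mouse 88. The 81 list calls of camera over the 8 comparisons became 1 with an estimated correlation and 14 with fry.

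With the animal as a block, brown adipose tissue and liver being paired by mouse, the tissue difference gave 3 genes in place of 4 on day 15 and 3 in place of 3 on day 29 (block correlation -0.0448). Pltp on day 15 was not called (adjusted p = 0.0604), and the block changed no other call among the 7 genes named for these differences.

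Leaving out each array in turn gave 339 to 1023 genes in white adipose tissue on day 15, 51 to 237 on day 29 and 125 (without day 15 vehicle mouse 48) to 716 (without day 15 fenretinide mouse 59) for the difference between days. In brown adipose tissue it gave 2 to 10 on day 15, 2 to 74 on day 29 and 0 to 0 between days. In liver it gave 4 to 6, 7 to 50 and 0 to 0 with troglitazone, and 0 to 0, 0 to 1 and 0 to 1 with Elmiron. The tissue difference ran from 1 to 4 on day 15 and from 1 (without liver vehicle mouse 83) to 30 (without brown adipose vehicle mouse 82) on day 29. The compound difference ran from 0 to 2 on day 15 and from 2 (without vehicle mouse 83 of the troglitazone study) to 23 (without Elmiron mouse 91) on day 29. Without Elmiron mouse 92 the 1 gene called on day 29 was not Id1.

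Without detection calls, which dim genes lie at background was not determined, so that changes of dim genes are limited by an unknown background.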

Other observations

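Further genes, among them Asns and Ddit3, were called with troglitazone in brown adipose tissue without mice 82 and 95. No hypothesis was tested here beyond the values given, and this fit and the genes of this paragraph were chosen after the results were seen. Genes of the unfolded protein and integrated stress response, which include Asns and Ddit3, did not shift as a list (18 measured, 1 higher and 1 lower on day 15, 1 higher and 2 lower on day 29, 1 higher and 2 lower and then 1 higher and 4 lower adjusted over the list alone, medians -0.03 and 0.01, camera adjusted p = 0.578 and 0.609). Asns, which makes asparagine, rose by 0.49 on day 15 (adjusted p = 5.33e-04, range over alternatives 1.14e-04 to 0.347) and by 0.39 on day 29 (0.0126, range 0.0126 to 1). The stress factor gene Ddit3 fell by 0.50 and 0.59 (0.0286 and 0.0218, ranges 0.0158 to 1 and 0.0205 to 1). The acute phase gene Orm3 fell by 1.15 and 1.37 (3.98e-04 and 4.61e-04, ranges 2.49e-05 to 0.283 and 1.35e-04 to 0.964). The glycerol channel gene Aqp7 rose by 0.50 on day 15 (0.0134, range 0.00198 to 0.433), and the endothelial protocadherin gene Pcdh12 fell by 0.55 and 0.96 (0.0181 and 9.48e-04, ranges 0.00527 to 0.906 and 4.09e-04 to 1). Collagen and matrix genes were called higher as a list on day 29 in that fit (23 measured, 1 higher, 8 adjusted over the list alone, median 0.35, camera adjusted p = 3.24e-07, 0.430 with an estimated correlation), as were macrophage markers (24 measured, 0 called, 7 adjusted over the list alone, median 0.37, 7.40e-05, 0.537 with an estimated correlation). The macrophage median was 0.23 without vehicle mouse 83 and 0.20 without vehicle mouse 85.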
